A study of Mus musculus with 32 samples.

How the data were processed

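The data are RNA sequencing of mouse MII oocytes, zygotes, early 2-cell, 2-cell, 4-cell and 8-cell embryos, ICM, R1 embryonic stem cells and siRNA-injected 8-cell embryos and blastocysts, 32 samples in all. Per the labels' protocols, oocytes came from C57BL/6N females and embryos from C57BL/6N females mated with DBA/2N males after hormone injection. The zona pellucida was removed, ICM was isolated by immunosurgery, injected embryos were cultured in CZB medium with glutamine, and libraries were made by Smart-seq2 with slight modification. Per the submitters' processing notes, bases were called with CASAVA 1.8 and reads aligned to mm9 with STAR 2.4.0 in all 32 samples. The same notes name Cufflinks 2.2.1 for 20 of the 32 samples and give no tool for the expression values of MII oocytes, early 2-cell embryos and the 8-cell knockdown libraries. The values are FPKM as deposited by the authors, in a stage table of 24013 genes with 1 column per stage and 2 knockdown tables of 22536 genes with 1 column per library. How the replicates of a stage became 1 column is not stated in the notes. The stage table had 30 cells without a value, all in MII oocytes, and 22515 genes were in both kinds of table. No column of values was left unused.

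Depth was not given as read totals. FPKM values below 0.4 fell on steps set by single fragments, and the ratio of these steps between libraries gave relative depth. In the 8-cell knockdown libraries all 28 pairs fitted within 1.26%. In the blastocyst libraries this held only within the libraries with Rn45s (6 pairs within 3.30%, 1.57-fold between deepest and shallowest) and those without (3 pairs within 0.250%, 1.76-fold), while across the types pairs were off by up to 41.6%. Totals of FPKM were 285293 to 308689 in the 8-cell knockdown libraries, 237292 to 366359 in the blastocyst libraries and 234738 (2-cell) to 495643 (MII oocyte) per stage. Correlations between replicates were 0.923 to 0.976 in the knockdown groups.

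Groups followed the labels. For each knockdown, genes with at least 1 FPKM in as many libraries as the smaller group holds were kept, values were taken as log2(FPKM + 1), and limma 3.58.1 with a trend in the prior variance compared knockdown with control (R 4.3.3). Adjusted p-values are Benjamini-Hochberg over all genes tested, with 0.05 as the threshold. Gene lists were written before the data were examined, as were the comparisons and the settings in them, except where stated otherwise. They were tested with limma's camera with a preset correlation of 0.01, which followed the variance trend of the fit; without the trend the adhesion list passed in the Nr5a2 knockdown (adjusted p = 0.0491). Lists with fewer than 5 measured genes were not tested. An estimated correlation was run beside the preset one, and fry, which tests whether a list's genes move on balance in 1 direction, called none of these lists in either knockdown. Exact permutation tests over all arrangements of the libraries, two-sided by counting the smaller tail 2 times, were used for the targeted genes and for list means per library. These p-values were not adjusted over the lists. Stage-derived lists held genes with a difference of at least 1 in log2(FPKM + 1) and at least 5 FPKM in the higher stage, and the same rule counted changed genes per stage step. For the stage steps each list's median difference was placed among 10000 random lists matched in 10 bins of expression, and 54 of 127 pairs of list and step lay outside percentiles 2.5 to 97.5. Genes of a random list were drawn independently, while genes of a real list can move together. A percentile is therefore a description and not a p-value. Other work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

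Named genes were chosen by a rule. It takes the targeted gene, and the 10 largest rises and 10 largest falls among genes with adjusted p under 0.05, at least 5 FPKM in the higher group and no overlap between the groups. It adds up to 4 members with the smallest p of each called list, a fixed set of lineage genes (Gata4, Gata6, Sox17, Pdgfra, Nanog, Sox2, Pou5f1, Cdx2, Krt8, Tfap2c, Gata3 and Cdh1), and for stage steps the 5 largest differences in each direction. Unnamed loci were passed over, and any member of a list may serve as an example.

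Near-identical copies were searched with minimap2 2.31, aligning coding sequences to all transcripts of GENCODE M21. Matching whole transcripts missed copies and was not used. Of 14242 genes with 1 FPKM or more somewhere, 13590 (95.42%) were found by symbol, and 1452 had another transcript at 95% identity or more over at least 50% of their length. Values of such genes are called uncertain, since reads can be assigned to either copy.

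The fits were tested on simulated data drawn with each gene's control mean and fitted spread. With 100 genes shifted by 1 log2 unit 51% were recovered in the 8-cell libraries and 19% in the blastocyst libraries, and with a shift of 2 log2 units 100% and 91%. Of the calls made, 5% and 12.7% were false. The simulated genes were independent, without the library types found in the blastocyst libraries. Only genes with a control mean above 2 in log2(FPKM + 1) were shifted. These rates therefore need not hold for the real blastocyst libraries or for low genes. The stage rule recovered 100% of 200 genes changed 4-fold between 2 copies of the 8-cell column. Such a change exceeds the rule's threshold, so this checks the calculation alone and not the error between stages.

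Lists with fewer than 5 measured genes are given by their highest FPKM in any library. In the 8-cell libraries, interferon response genes reached 38.2 FPKM (Bst2), genes bound by NR5A2 in liver or gonad 21.0 (Apoa1), cumulus and granulosa genes 0.259 (Star), sperm genes 4.68 (Ldhc), fibroblast genes 7.03 (Loxl1) and blood genes 68.2 (Cd74). In the blastocyst libraries, 2-cell-stage genes reached 5.52 (Tdpoz2), interferon response genes 50.1 (Bst2), genes bound by NR5A2 in liver or gonad 117 (Apoa1), cumulus and granulosa genes 18.6 (Cyp11a1), sperm genes 1.79 (Tnp2), fibroblast genes 3.29 (Fn1) and blood genes 12.5 (Cd68).

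The alternatives were pseudocounts of 0.1 and 5, no filter, a mean of at least 5 FPKM, median scaling, quantile normalization, no variance trend, the replicate number as a block, other list tests and stage thresholds, 20 bins, and leaving out each library. The library type given by Rn45s was found in the data, so fits with the type as a covariate and fits within a type were added later, as were some of the scalings and filters for the lists.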

Results

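Gene expression was measured by RNA sequencing of polyadenylated RNA in mouse oocytes, preimplantation embryos and embryonic stem cells. Libraries were made by a modified Smart-seq2 protocol, a full-length cDNA method for very small numbers of cells. The authors deposited FPKM values (fragments per kilobase of transcript, scaled to depth) for 32 samples in 3 tables. The stage table covered MII oocytes (2 samples), zygotes (2), early 2-cell (2), 2-cell (2), 4-cell (2) and 8-cell embryos (2), the inner cell mass (ICM) isolated from blastocysts by immunosurgery (3) and the R1 line of mouse embryonic stem cells (mESC, 2), with 1 deposited value per gene and stage. The knockdown tables held 1 column per library, with 4 control and 4 Nr5a2 knockdown libraries of 8-cell embryos, and 3 control and 4 Gata4 knockdown libraries of blastocysts, all from siRNA-injected embryos. Between 7703 and 8370 genes reached 1 FPKM per library in the 8-cell knockdown table, between 7378 and 8945 in the blastocyst table, and between 8388 and 9580 per stage. Read totals were not used here. The steps between low FPKM values gave the 8-cell libraries relative depths of 1.52, 2.66, 1.0 and 1.25 for controls 1 to 4 and of 2.89, 1.42, 1.69 and 1.84 for knockdowns 1 to 4, with the shallowest library set to 1. The labels name no separate cultures or litters, so p-values measured only the spread between these samples, which may be technical.

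The Nr5a2 knockdown asked which genes depend on this orphan nuclear receptor, a transcription factor of the early embryo and of liver and gonad, at the 8-cell stage. Nr5a2 itself stood at 23.6, 20.3, 13.1 and 25.2 FPKM in the 4 control libraries and at 3.76, 4.25, 6.72 and 6.60 FPKM in the 4 knockdown libraries. Its mean fell from 20.6 ± 5.39 to 5.33 ± 1.54 FPKM (SD, n = 4 each), a log2 fold change of -1.76 (SE 0.27, limma adjusted p = 0.0143). A two-sided exact permutation test gave p = 0.0286, the smallest that 70 arrangements allow. Without control 1 the adjusted p was 0.0611, and without a filter on low values 0.0845. Of 8170 genes tested, 128 rose and 57 fell in the knockdown (7 and 4 without the filter).

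Among the genes that fell most were Fdx1, the mitochondrial ferredoxin that passes electrons to steroid-forming P450 enzymes, from 56.0 ± 15.5 to 6.83 ± 3.39 FPKM (log2 fold change -2.92, SE 0.31, adjusted p = 0.00182), and Kifc3, a minus-end-directed kinesin, from 49.9 ± 11.5 to 8.2 ± 2.59 FPKM (-2.48, SE 0.25, adjusted p = 0.00182). Khdc3, a component of the subcortical maternal complex, fell from 387 ± 104 to 70.1 ± 92.5 FPKM (-3.26, adjusted p = 0.0346), and Gata1, a transcription factor best known from red blood cells, fell from 24.9 ± 4.83 to 4.09 ± 3.49 FPKM (-2.64, adjusted p = 0.0193). Khdc3 stood at 208 FPKM in knockdown 3 and kept its call in 1 of 8 fits with 1 library left out. Tex264, an endoplasmic reticulum protein, Actn2, an alpha-actinin, Ssbp4 and the activin-binding protein Fstl3 fell by 2.14, 2.11, 2.10 and 2.06 on the log2 scale. The Nodal co-receptor gene Tdgf1 (58.5 ± 24.1 to 2.16 ± 2.34 FPKM, log2 fold change -4.44, adjusted p = 0.00182) and the threonine dehydrogenase gene Tdh (37.6 ± 27.7 to 2.51 ± 2.52 FPKM, -3.50, adjusted p = 0.0138) lay lower by more than any other named gene. Both are uncertain, since 99.8% of each coding sequence is shared with a near-identical pseudogene.

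Brdt, a bromodomain gene best known from the testis, rose from 1.16 ± 0.266 to 15.4 ± 7.90 FPKM (log2 fold change 2.81, SE 0.32, adjusted p = 0.00292). Dnajb14, a chaperone cofactor of the endoplasmic reticulum, rose from 8.15 ± 4.19 to 50.5 ± 14.5 FPKM (2.56, adjusted p = 0.00942), and Ube2e3, a ubiquitin-conjugating enzyme, from 21.2 ± 6.23 to 102 ± 40.6 FPKM (2.16, adjusted p = 0.0138). Slc2a3, a glucose transporter, rose from 4.57 ± 4.18 to 28.7 ± 12.4 FPKM (2.56, adjusted p = 0.0170), and Scd2, a fatty acid desaturase, from 1.76 ± 1.81 to 16.1 ± 10.5 FPKM (2.57, adjusted p = 0.0395). Khdc1b, Dynap and Fam154a rose by 2.56, 2.68 and 2.38 on the same scale. Dusp6, a phosphatase that switches off ERK, was listed at 0 in controls 1, 2 and 3 and at 0.218 FPKM in control 4, against 23.2, 3.24, 11.8 and 1.05 FPKM in knockdowns 1 to 4 (adjusted p = 0.0441).

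**Figure D1:**
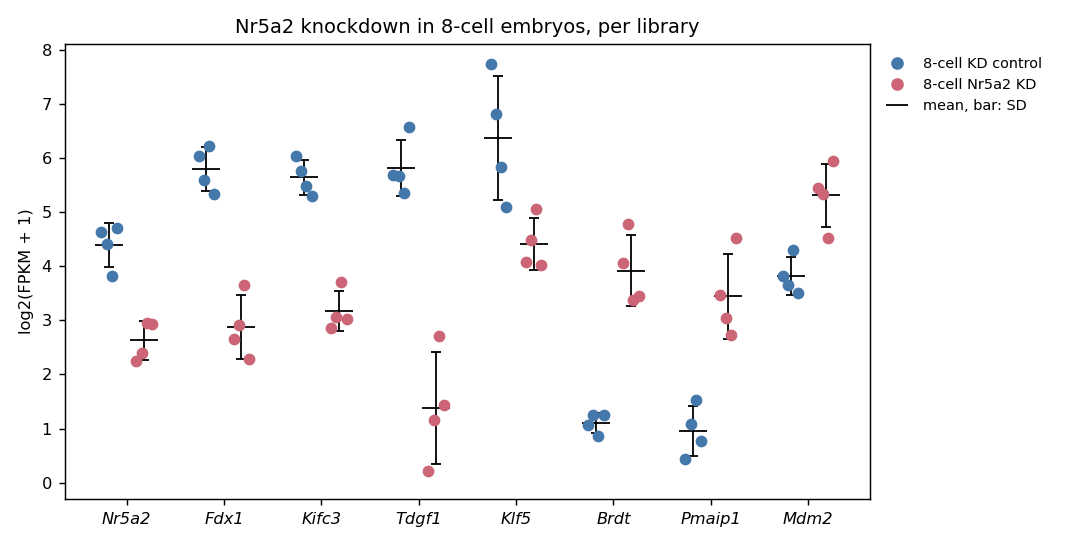
Expression of 8 genes as log2(FPKM + 1) on the vertical axis in the 4 control (blue) and 4 Nr5a2 knockdown (red) libraries of 8-cell embryos, with horizontal lines at the mean and bars of 1 SD. The 2 groups do not overlap for Nr5a2, Fdx1, Kifc3, Tdgf1, Klf5, Brdt, Pmaip1 or Mdm2; Klf5 missed the threshold (adjusted p = 0.0558).

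The test was limma on log2(FPKM + 1), so these fold changes understate the change of low genes, with Benjamini-Hochberg adjustment. The median of all 8170 genes lay 0.12 higher in the knockdown, which median scaling moved to 0.02. With it 75 genes were called higher and 80 lower in place of 128 and 57; quantile normalization called 68 and 71. Of the named genes called, Dynap lost its call with median scaling (adjusted p = 0.0527), where Dusp6 was not tested. Dynap and Scd2 lost it with a pseudocount of 0.1 (0.0556 and 0.0524), and Dynap, Dusp6 and Fam154a with a pseudocount of 5 (0.0623, 0.0929 and 0.0569). Without a filter on low values only 7 genes were called higher and 4 lower, so many of the named genes lost the call there. The replicate number as a block called 37 higher and 18 lower. The total depended on single libraries: 21, 47, 73 and 102 genes were called without control 1, 2, 3 or 4, and 86, 39, 285 and 92 without knockdown 1, 2, 3 or 4. Brdt, Dnajb14, Tdgf1, Tdh, Fdx1 and Kifc3 were called in all 8 fits with 1 library left out, while the rest of the 22 named genes called besides Nr5a2 lost the call in at least 1. The highest adjusted p of these was between 0.0525 and 0.134, without control 1 for all but Fam154a and Rpl15, where it was without control 2.

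Genes of the p53 response lay higher as a group. Of 19 measured, 17 had a positive fold change, with a median of 0.60, and 2 rose over all genes tested, or 3 when adjusted over the list alone. Pmaip1, which encodes the cell death factor Noxa, rose from 1.01 ± 0.652 to 11.2 ± 7.37 FPKM (log2 fold change 2.49, adjusted p = 0.0143), and Mdm2, the ubiquitin ligase that limits p53, from 13.4 ± 3.69 to 41.0 ± 15.6 FPKM (1.49, adjusted p = 0.0343). Btg2, an antiproliferative gene, stood at 2.00 ± 1.87 and 8.2 ± 2.24 FPKM (adjusted p = 0.0527), and Cdkn1a, a cyclin-dependent kinase inhibitor, at 97.1 ± 41.0 and 161 ± 43.3 FPKM (adjusted p = 0.185). The list passed limma's camera test (adjusted p = 0.00446), with adjusted p = 0.562 with an estimated correlation and a two-sided exact permutation p of 0.0857 on its mean per library.

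Genes of pluripotency and the epiblast lay lower as a group (camera adjusted p = 0.0136; adjusted p = 0.562 with an estimated correlation and 0.124 without a filter on low values). Of 17 measured, 12 had a negative fold change, with a median of -0.23. Over all genes tested 1 fell (Tdgf1), and 1 rose and 4 fell when adjusted over the list alone. Klf5, a Krüppel-like transcription factor of the early blastomeres, stood at 103 ± 79.3 FPKM in controls and 21.1 ± 7.88 in knockdowns (-1.96, adjusted p = 0.0558). Pou5f1 (Oct4) stood at 147 ± 44.9 and 72.8 ± 49.4 FPKM (-1.27, adjusted p = 0.175), and Nanog at 7.92 ± 4.90 and 3.02 ± 2.68 FPKM (-1.23, adjusted p = 0.276). Dppa5a, uncertain because of near-identical copies, had a fold change of -0.74 (adjusted p = 0.119). Stat3, a signal transducer of the LIF pathway, stood at 0.937 ± 0.461 and 3.73 ± 2.2 FPKM (adjusted p = 0.0887). The list's mean relative to all genes was lower in each knockdown library (0.51 to 0.95) than in any control library (1.18 to 1.47; two-sided exact permutation p = 0.0286, the smallest possible). That p is not adjusted over the lists tested, and the mean includes the uncertain genes Tdgf1 and Dppa5a.

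Of 75 measured cytosolic ribosomal proteins, 51 had a negative fold change, with a median of -0.08, and 1 fell (Rpl15, 7.0 ± 1.82 to 2.44 ± 0.644 FPKM, adjusted p = 0.0403), as when adjusted over the list alone. Rpl15, Rpl27a (-1.13), Rpl17 (-0.66) and Rpl27 (-0.67) all have near-identical copies and are uncertain. The list passed camera (adjusted p = 0.00446; adjusted p = 0.757 with an estimated correlation), except without knockdown 1 (adjusted p = 0.0754), and a two-sided exact permutation test on its mean per library gave p = 0.0571. Of 25 genes of ribosome biogenesis and the nucleolus, 17 had a negative fold change, with a median of -0.14 (adjusted p = 0.0194; adjusted p = 0.660 with an estimated correlation). None of them passed in limma, where 1683 of all 8170 genes had an unadjusted p under 0.05, and none did when adjusted over the list alone. Its examples were Bysl (-0.47), the RNA polymerase I factor Ubtf (-0.46), Rrp9 (-0.46) and Nop10 (0.44). The call was lost without control 1 (adjusted p = 0.0589), control 4 (0.0893), knockdown 2 (0.114) or knockdown 3 (0.0813). A two-sided exact permutation test on this list's mean per library gave p = 0.143, with overlapping groups.

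**Figure D2:**
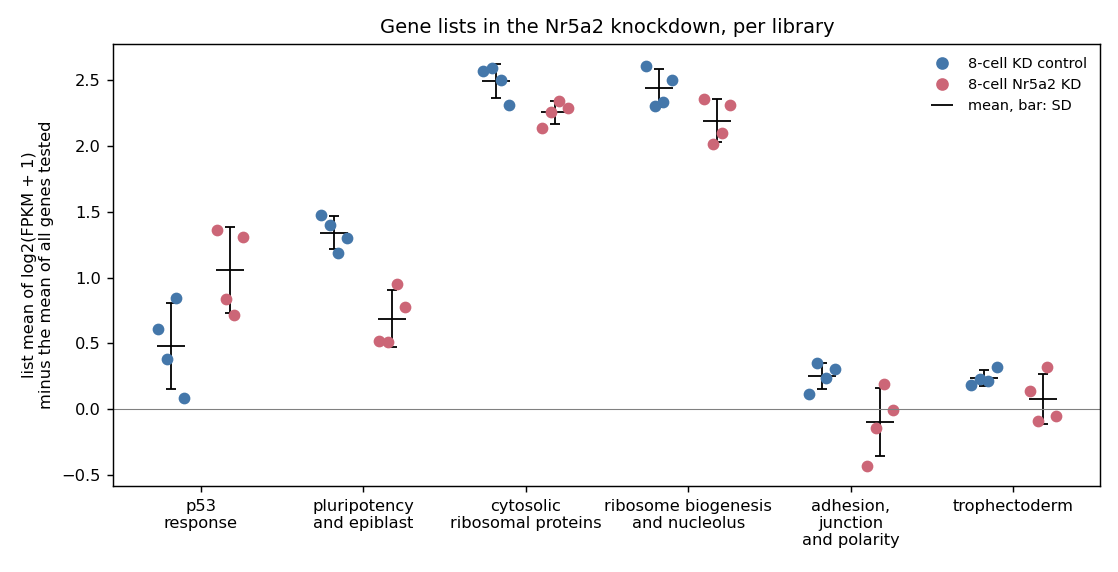
Mean of log2(FPKM + 1) over the measured genes of 6 lists minus the mean of all genes tested (vertical axis, log2 units), per library, in 4 control (blue) and 4 Nr5a2 knockdown (red) libraries, with lines at the mean and bars of 1 SD. The pluripotency list was lower in every knockdown library than in any control library, while the groups overlapped for the other 5 lists.

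The other lists missed the threshold of an adjusted p of 0.05. Adhesion, junction and polarity genes had a median fold change of -0.15 (adjusted p = 0.0583; 0.0230 without control 1 and 0.0491 without the variance trend). Among them were the tight junction gene Cldn4 at 86.9 ± 41.2 and 30.9 ± 17.4 FPKM (adjusted p = 0.0962) and the cadherin Cdh1 at 21.3 ± 1.29 and 15.3 ± 5.62 FPKM (adjusted p = 0.308). Trophectoderm genes (adjusted p = 0.216) went both ways, with Gata3 at 2.12 ± 1.36 and 9.04 ± 3.77 FPKM (adjusted p = 0.0557), Krt8, uncertain because of a partial copy, at 11.3 ± 10.4 and 21 ± 4.84 FPKM (adjusted p = 0.194), Tead4 at 90.1 ± 27.8 and 53.8 ± 25.4 FPKM (adjusted p = 0.177) and Tfap2c at -0.42 on the log2 scale. When adjusted over the list alone, 1 trophectoderm gene rose and 2 fell. Primitive endoderm (adjusted p = 0.260; Gata4 -0.27, Gata6 -0.42), 2-cell-stage (0.975), mitosis (0.628) and housekeeping genes (0.654) also missed it. Oocyte-expressed maternal genes (adjusted p = 0.145) passed without control 2 (0.0451), and oxidative phosphorylation genes (adjusted p = 0.145, median 0.19) passed without control 2 (0.0133), without knockdown 1 (0.0157) and with quantile normalization (0.0396). Sqle, the squalene epoxidase, rose from 6.44 ± 2.17 to 28.8 ± 11.4 FPKM (adjusted p = 0.0143) in a cholesterol synthesis list that did not pass (adjusted p = 0.759, with 3 rising when adjusted over the list alone). Slc2a3 was the 1 glycolysis gene to rise (list adjusted p = 0.759), and the proteasome subunit Psmd14 rose by 0.73 (list adjusted p = 0.454). Among imprinted genes Impact rose by 1.85, and 1 rose and 2 fell when adjusted over the list alone. That list (median 0.12, adjusted p = 0.759) and the DNA methylation list (median 0.07, adjusted p = 0.782) had positive medians while their tests pointed down. With quantile normalization both medians were negative (-0.02 and -0.01). Sox17, Sox2, Pdgfra and Cdx2 were below the expression filter.

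To ask whether the knockdown moved genes of the normal 4-cell to 8-cell step, gene lists were taken from the stage table, whose libraries are separate. Of 378 measured genes that were higher at the 8-cell than at the 4-cell stage, 7 rose and 13 fell in the knockdown, or 14 and 22 when adjusted over the list alone. The list ranked lower than other genes (median -0.04, adjusted p = 0.00176; adjusted p = 0.231 with an estimated correlation). Without knockdown 1 its median was 0.04 and adjusted p = 0.0284. Of 476 that were lower at the 8-cell stage, 17 rose and 1 fell, or 27 and 3 when adjusted over the list alone (median 0.22, adjusted p = 0.0767; 0.231 with an estimated correlation, 0.0363 with median scaling, 0.0481 without control 1, 0.0397 without knockdown 3 and 0.0336 without knockdown 4). The 57 genes that fell included 13 of the stage-rising genes where 2.64 would be shared by chance (Fisher's exact p = 1.39e-06), among them Fdx1, Khdc3, Fstl3, Crip2, Tfeb and Tdh. The 128 that rose included 17 of the stage-falling genes where 7.46 would be (Fisher's exact p = 0.00159), among them Mdm2, Khdc1b, Hmox1 and Bcl2l11. Genes are not independent of each other, so these p-values describe the overlap only.

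The Gata4 knockdown asked which genes depend on this zinc finger transcription factor, a marker of the primitive endoderm, in blastocysts. Gata4 stood at 3.18, 0.716 and 5.44 FPKM in the 3 control libraries and was listed at 0, 0.368, 0 and 0 FPKM in the 4 knockdown libraries. A two-sided exact permutation test gave p = 0.0571, which counts the smaller tail of the 35 arrangements 2 times; it is the smallest p that this way of counting allows. The gene was below the expression filter of the main fit. Without control 2, its lowest control, it passed the filter with a log2 fold change of -2.26 and limma adjusted p = 0.0008. Leaving out the lowest control widens the difference, so this p adds no support. With no filter the fold change was -1.73 (limma adjusted p = 1).

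These 7 libraries were of 2 types. Rn45s, the ribosomal RNA precursor, was listed at 0 in control 2, knockdown 1 and knockdown 2 and between 37959 and 44718 FPKM in the other 4 libraries. With the knockdown in the model, 4496 of 8782 genes differed between the types (4482 lower and 14 higher with Rn45s, adjusted p under 0.05). Within the 4 libraries with Rn45s (2 and 2), the Gata4 difference was -2.38 (limma adjusted p = 0.1004), and within the 3 without it was -0.55 on the log2 scale. The type without Rn45s holds 1 control, so values within it cannot be told from that single library.

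Of 8782 genes tested, 0 rose and 3 fell (limma; 202 at unadjusted p under 0.05). Aqp8, a water channel on the trophectoderm list, stood at 5.94, 4.00 and 15.1 FPKM in the controls and at 0.156, 0.277, 0.630 and 0 FPKM in the knockdowns (log2 fold change -2.72, SE 0.39, adjusted p = 0.00085; -3.05 with Rn45s and -2.04 without). Timp1, an inhibitor of matrix metalloproteinases, stood at 11.2, 9.64 and 9.72 FPKM and at 0.655, 4.12, 0.235 and 0 FPKM (-2.63, SE 0.44, adjusted p = 0.00754; -3.36 with Rn45s and -1.87 without). The third was an unnamed locus and was passed over. Without control 1 the adjusted p of Timp1 was 0.0767, and with a pseudocount of 0.1 it was 0.149. Median scaling and quantile normalization each called 0 genes (505 and 484 at unadjusted p under 0.05), as did the library type as a covariate (704). The fold changes of Aqp8 and Timp1 stayed at -2.69 each with median scaling (adjusted p = 0.486 each). Fits without 1 library called 0 higher and 1, 4 or 10 lower without control 1, knockdown 3 or control 3, 2 higher and 9, 25 or 11 lower without knockdown 1, 2 or 4, and 5 higher and 19 lower without control 2.

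Primitive endoderm genes lay lower as a group. Of 17 measured, 12 had a negative fold change, with a median of -0.90; 0 fell over all genes tested (202 at unadjusted p under 0.05) and 9 when adjusted over the list alone (limma). Lamc1, a laminin chain of the basement membrane, stood at 8.2 ± 2.36 FPKM in controls and 2.82 ± 1.51 in knockdowns (-1.33; -1.96 with Rn45s and -0.52 without), with no overlap between the groups. The collagen chaperone Serpinh1 stood at 6.18 ± 4.17 and 1.23 ± 1.05 FPKM (-1.61; -2.29 and -0.46), the laminin Lama1 at 6.34 ± 5.19 and 1.13 ± 0.677 FPKM (-1.56; -2.49 and -0.05) and the collagen Col4a1 at 4.98 ± 3.90 and 0.978 ± 0.925 FPKM (-1.48; -2.24 and -0.24). Sox17 stood at 0.626, 0.383 and 0.952 FPKM in controls and was listed at 0, 0.121, 0 and 0 FPKM in knockdowns. Gata6, an earlier factor of the lineage, did not differ detectably (15.3 ± 9.49 and 16.9 ± 10.2 FPKM, 0.09). The list passed camera (adjusted p = 1.75e-12; adjusted p = 0.442 with an estimated correlation), also within the libraries with Rn45s (median -1.43, adjusted p = 2.65e-07) but not within those without (median -0.17, adjusted p = 0.898). The list's mean relative to all genes was 0.28, -0.43 and 1.03 in controls 1 to 3 and -0.59, -0.27, -0.18 and -0.52 in knockdowns 1 to 4, so control 2 lay below knockdowns 2 and 3 (two-sided exact permutation p = 0.171). Without control 3, the highest, the median was -0.50 (adjusted p = 0.00035). Serpinh1, Lama1 and Col4a1 were also lower in control 2 than in knockdown 2.

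**Figure D3:**
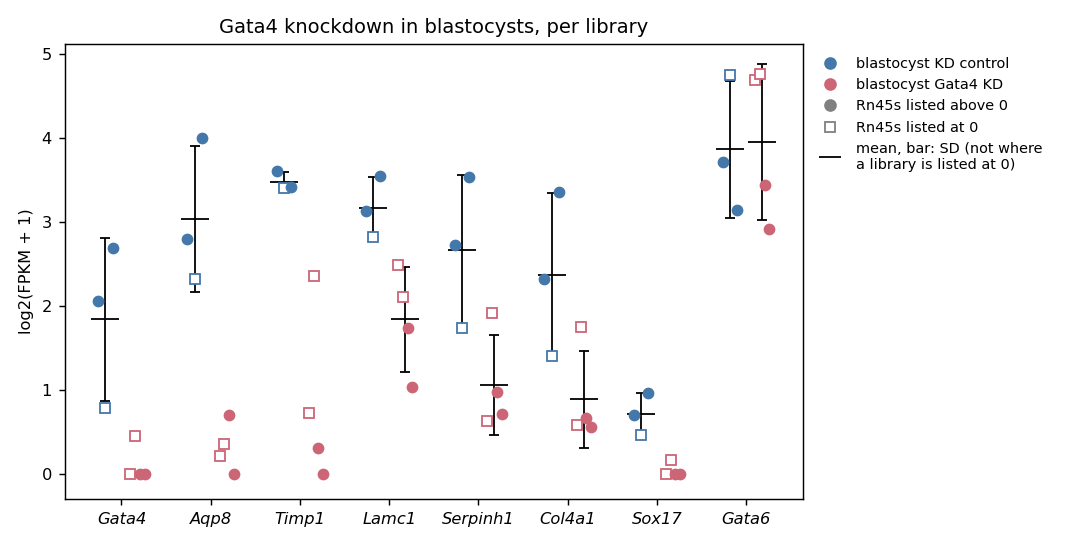
Expression of 8 genes as log2(FPKM + 1) on the vertical axis in 3 control (blue) and 4 Gata4 knockdown (red) blastocyst libraries, as filled circles where Rn45s was listed above 0 and open squares where it was listed at 0. Lines and bars give the mean and 1 SD except in groups with a library listed at 0. Gata4, Aqp8, Timp1, Lamc1 and Sox17 do not overlap between the groups, while the groups overlap for Gata6.

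Cholesterol synthesis genes also lay lower (median -0.50, adjusted p = 4.25e-06; adjusted p = 0.850 with an estimated correlation), with 0 of 21 falling over all genes and 1, Sqle, when adjusted over the list alone. Sqle stood at 11 ± 3.81 and 2.79 ± 1.31 FPKM (-1.68; -2.29 with Rn45s and -0.86 without), and the list passed with Rn45s (adjusted p = 0.000602) but not without (adjusted p = 0.578). Trophectoderm genes (24 measured, median -0.21, adjusted p = 0.00265; 0.862 with an estimated correlation) included Aqp8 as the 1 that fell on either adjustment, and the list passed within neither type (adjusted p = 0.268 and 0.159). Cdx2, Krt8, Tfap2c and Gata3 had fold changes of -0.21, 0.00, 0.09 and -0.21. Pluripotency genes (20 measured, median -0.20, adjusted p = 0.0225; 0.862 with an estimated correlation), with 0 called on either adjustment, gave adjusted p = 0.268 with Rn45s, and 2.97e-05 without it against the single control. Spp1, osteopontin, stood at 108, 122 and 47.2 FPKM in controls and 65.5, 90.7, 2.80 and 0.250 in knockdowns (-2.73, adjusted p = 0.718), while Nanog and Pou5f1 had fold changes of -0.15 and 0.37. Two-sided exact permutation tests on the list means per library gave p = 0.171 (cholesterol synthesis), 0.4 (trophectoderm) and 0.286 (pluripotency), with overlapping groups.

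Genes of 3 housekeeping systems lay slightly higher, with 0 genes called on either adjustment. The medians were 0.20 for 69 ribosomal proteins (adjusted p = 7.78e-05), 0.20 for 53 oxidative phosphorylation genes (adjusted p = 0.00265) and 0.24 for 31 proteasome subunits (adjusted p = 0.00265), each with adjusted p = 0.862 with an estimated correlation. In that order, two-sided exact permutation tests on the list means per library gave p = 0.229, 0.343 and 0.343, with overlapping groups. Within the libraries with Rn45s the camera adjusted p-values of ribosomal proteins, oxidative phosphorylation and proteasome were 8.98e-07, 0.0162 and 0.00355. Within those without Rn45s the proteasome test pointed in the opposite direction. Examples were Ndufa6 (409 ± 165 and 587 ± 55.2 FPKM), Cox6b1 (866 ± 297 and 1172 ± 375 FPKM) and Psma7 (398 ± 188 and 520 ± 203 FPKM). Quantile normalization ended the calls of oxidative phosphorylation (adjusted p = 0.471, with its test pointing down) and the proteasome (adjusted p = 0.193), and median scaling that of pluripotency (0.0825), which was also lost with a mean of at least 5 FPKM (0.0524). The trophectoderm list lost its call without a filter (0.0905) and with the library type as a covariate (0.189). Without control 3 the calls of ribosomal proteins (adjusted p = 0.582), oxidative phosphorylation (0.559), proteasome (0.660) and trophectoderm (0.660) were lost. Cholesterol synthesis was lost without control 1 (0.0881), pluripotency without control 1 (0.0861), control 2 (0.483) or knockdown 4 (0.246), and oxidative phosphorylation also without knockdown 4 (0.0738). The primitive endoderm list passed in all 7 of these fits. Most other splits of these libraries also gave it an unadjusted camera p under 0.05 (smallest 1.68e-18). Its passes therefore add little support. The remaining lists missed the threshold: ribosome biogenesis (adjusted p = 0.0780; 0.0230 with median scaling, 0.00740 with quantile normalization 0.00279 with the library type as a covariate and 0.0237 without control 3), maternal (0.689, with a median of 0.15 and a mean of -0.01), adhesion (0.197; 0.0481 with quantile normalization and 0.0373 with a mean of at least 5 FPKM), p53 response (0.551; 0.0446 without Rn45s), DNA methylation (0.197), glycolysis (0.490), mitosis (0.869, with a median of -0.06 and a test pointing up), imprinted (0.978, with a median of 0.17 and a mean of -0.11) and housekeeping genes (0.197). Genes higher in the ICM than at the 8-cell stage (1641 measured, median -0.03, adjusted p = 0.163) and genes lower there (1197 measured, median 0.03, adjusted p = 0.0861) missed it too. With quantile normalization both passed (0.0190 each), the first passed without control 3 (0.00701) and the second without control 2 (0.0119). With an estimated correlation both gave adjusted p = 0.851.

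The stage table gave the course of expression from oocyte to ICM and in mESC. Its values are the authors' single value per stage, so no error or test applies, a difference is between deposited values, and a 0 may be a failed estimate. Nr5a2 stood at 3.46, 3.59 and 3.30 FPKM in oocyte, zygote and early 2-cell embryo, at 26.9, 48.1 and 38.4 FPKM in 2-cell, 4-cell and 8-cell embryos, and at 4.65 and 2.48 FPKM in ICM and mESC. Gata4 stood at 4.57, 2.08 and 3.59 FPKM, then at 17.6, 17.7 and 8.04 FPKM, and at 5.44 FPKM in the ICM, and was listed at 0 in mESC.

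The median of oocyte-expressed maternal genes was highest in the MII oocyte and lower at each later stage, though not every member was, such as Khdc3 (5.74 FPKM in the oocyte and 611 in the ICM). The median was 617 FPKM in the oocyte, 297 in the zygote, 187 in the early 2-cell, 23.2 in the 2-cell, 10.2 in the 4-cell and 2.97 in the 8-cell embryo. From oocyte to zygote 784 genes were at least 1 log2 unit higher and 1352 lower (36.7% higher; 45.8% with median scaling and 52.2% with quantile normalization, where the all-gene median moved from -0.24 to -0.14 and -0.07). Mos, the kinase that holds the oocyte in metaphase, stood at 436 FPKM in the oocyte and 10.7 FPKM in the zygote. Genes of the 2-cell stage stood out from zygote to early 2-cell embryo, with medians of 0.349 and 33.1 FPKM. They included Zscan4f (1.74 and 136 FPKM, uncertain because of near-identical copies) and Zfp352 (0.676 and 78.0 FPKM), a zinc finger gene. Over that step 315 genes were higher and 504 lower (38.5% higher; 56.0% with median scaling, where the all-gene median moved from -0.07 to 0.06; 106 and 42 with a difference of at least 2).

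The early 2-cell to 2-cell step was the largest, with 2519 genes higher and 2489 lower (2250 and 2938 with median scaling). Median scaling moved the all-gene median of that step from -0.12 to -0.30. The notes name no expression tool for MII oocytes and early 2-cell embryos, but name Cufflinks for zygotes and 2-cell embryos. Rn45s was listed at 6829 FPKM in the early 2-cell and 0 in the 2-cell embryo. Oaz1-ps, which has a near-identical copy, stood at 0.000404 and 311 FPKM. In the steps on either side of the zygote, and in this step, processing therefore cannot be told apart from development. Of 78 cytosolic ribosomal proteins 75 were at least 1 log2 unit higher, and their median went from 5.46 to 73.6 FPKM, values that are uncertain for the many with near-identical copies. Ribosome biogenesis genes (22 of 25 higher, medians 5.82 and 23.2 FPKM) and oxidative phosphorylation genes (33 of 54 higher, medians 16.8 and 39.0 FPKM) moved the same way, while 24 of 30 maternal genes were lower. Single genes included the lysosomal protease Ctsc (1.02 and 284 FPKM) and the small GTPase Rab20 (0.518 and 249 FPKM). At the 2-cell to 4-cell step 1581 genes were higher and 1136 lower (1259 and 1243 with median scaling, and 241 and 352 with a difference of at least 2), with 66 of the 78 ribosomal proteins higher and 19 of 30 genes of the 2-cell stage lower. Hand1, a basic helix-loop-helix factor of trophoblast, stood at 4.00 and 119 FPKM, and Tcl1b3, of an oocyte-expressed cluster, at 223 and 3.58 FPKM. From 4-cell to 8-cell 414 genes were higher and 583 lower (443 and 459 with median scaling, and 87 and 66 with a difference of at least 2), with Crip2 at 4.41 and 106 FPKM and Cdh1 at 7.67 and 23.8 FPKM. Adhesion, junction and polarity genes (23 measured, 6 higher and 0 lower) lay above 10000 of 10000 matched random lists.

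From 8-cell to ICM 1837 genes were higher and 1447 lower (1572 and 1546 with median scaling), and lists of all 3 blastocyst lineages had higher medians, with genes going both ways. Pluripotency genes (17 higher and 1 lower of 25) had medians of 7.39 and 30.2 FPKM, with Nanog at 6.59 and 288 FPKM and Sox2 at 0.110 and 8.03 FPKM. Primitive endoderm genes (10 higher and 1 lower of 22) included Sparc, an extracellular matrix protein (0.554 and 195 FPKM), and the receptor Pdgfra (0.866 and 16.2 FPKM), in ICM isolated by immunosurgery. Trophectoderm genes (9 higher and 4 lower of 22) included the keratin Krt8 (1.33 and 62.7 FPKM, uncertain because of a partial copy) as well as Hand1 (102 and 7.92 FPKM) and Tead4 (42.6 and 7.20 FPKM). The stages include no trophectoderm or whole blastocyst. Trophectoderm carried over in immunosurgery therefore cannot be told apart from expression in the ICM. Spp1 went from 0.173 to 2088 FPKM, and Upp1, a uridine phosphorylase, from 1.53 to 571 FPKM, while Alppl2, an alkaline phosphatase, went from 2557 to 24.9 FPKM. Glycolysis (13 of 17 higher) and oxidative phosphorylation genes (32 of 54 higher) were higher and mitosis genes lower (1 higher and 10 lower of 26). Housekeeping genes, which share members with the first 2 lists, also had a higher median (108 and 325 FPKM). Between ICM and mESC, 725 genes were higher and 2527 lower in mESC (22.3% higher), but median scaling gave 1698 and 1160 (59.4%) and quantile normalization 1383 and 1333 (50.9%), as the all-gene median moved from -0.44 to 0.15 and 0.01. Rn45s was listed at 0 in the ICM and at 2555 FPKM in mESC, so a difference in processing cannot be excluded for this step either. Primitive endoderm genes were lower in mESC (0 higher and 14 lower of 22), with Gata6 at 16.4 and 0.0851 FPKM and Pdgfra at 16.2 and 0.0200 FPKM.

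**Figure D4:**
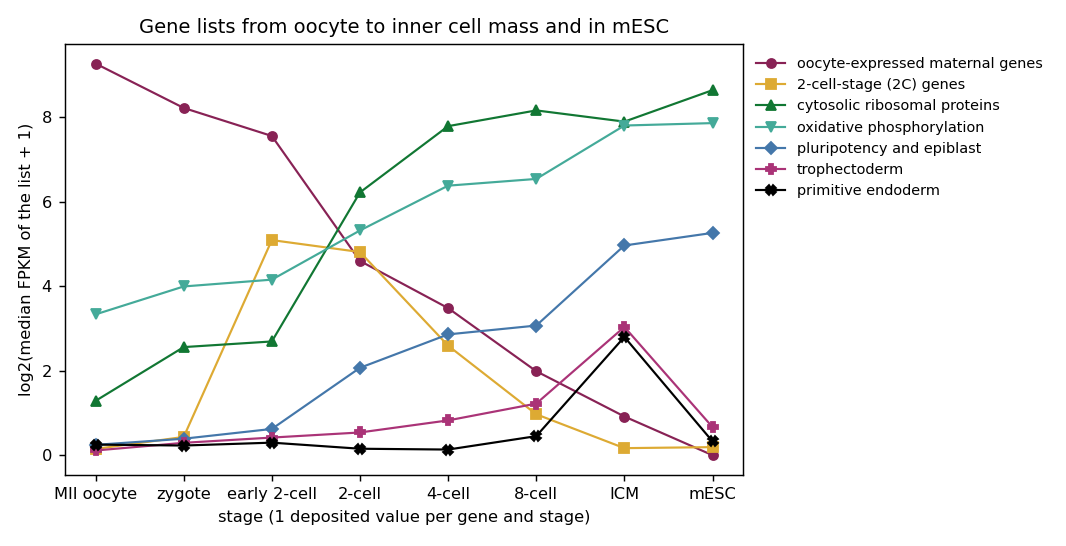
Median FPKM of 7 gene lists, as log2(median + 1) on the vertical axis, at the 8 stages of the deposited stage table on the horizontal axis, with 1 value per stage and no error bars. The maternal list was highest in the MII oocyte (617 FPKM), the 2-cell-stage list in the early 2-cell embryo (33.1 FPKM), and the primitive endoderm and trophectoderm lists in the ICM (5.96 and 7.20 FPKM). The stages include no trophectoderm or whole blastocyst.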

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

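The tests of a copy, of the library type, of a different scale and of other splits of the libraries were chosen after the result was seen; those of slower development and of a change particular to the injected 8-cell embryos were set beforehand.

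A library lay far from the other 3 of its group for 6 of 134 gene and group pairs tested with Dixon's ratio. For independent values with a normal spread chance gives about 6.7. Ratios of 1.0 arose where the other 3 libraries were listed at 0, so this number decides nothing about chance. Knockdown 2 of the Gata4 comparison was the highest of its group for Gata4 (0.368 FPKM against 0 in the others, ratio 1.0), Sox17 (0.121 FPKM against 0, ratio 1.0), Pdgfra (1.26 FPKM against 0 to 0.0151, ratio 0.982) and Col4a1 (2.36 FPKM against 0.468 to 0.583, ratio 0.909). In the 8-cell controls, Dusp6 in control 4 (0.218 FPKM against 0) and Sox2 in control 1 (0.148 FPKM against 0) each had a ratio of 1.0.

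The blastocyst libraries split by Rn45s, listed at 0 in control 2 and knockdowns 1 and 2, and the split carried the first principal component (60.6% of the variance). With the knockdown in the model 4496 genes differed between the types, which argues against the Gata4 knockdown itself as the source of the split. After each library was divided by its median, 1 gene differed, with a spread of 0.443 in place of 0.46 (SD of log2 differences over genes) around a median of -0.05 in place of -0.64. Median scaling removes a shift common to most genes whatever its source, so the drop to 1 gene cannot single out a different scale. A different scale of the FPKM values in the 2 types stays a candidate explanation, and why the scale would differ was not tested.

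Genes that rise from 4-cell to 8-cell ranked lower than other genes in the Nr5a2 knockdown (adjusted p = 0.00176; adjusted p = 0.231 with an estimated correlation; median -0.04, and 0.04 without knockdown 1). Median scaling gave an adjusted p of 0.00284, but the test compares the list with other genes and is hardly moved by 1 factor per library, so it decides nothing about a different scale of the FPKM values in the 2 groups. Slower development of the knockdown embryos may contribute: the rising minus falling score was 1.34 ± 0.12 in controls and 1.03 ± 0.26 in knockdowns (exact permutation p = 0.0857; smallest possible 0.0286). The bound set beforehand against it, overlapping groups and a p of 0.05 or more, was met, but a missed p in 4 against 4 libraries excludes nothing, and knockdowns 1 and 2 (0.71 and 0.93) lay below every control (lowest 1.21). It therefore cannot be told apart from a direct effect of NR5A2 here, and 6 of the 35 splits of the 8 libraries, the real one included, gave a p as small (real p 0.000882, smallest other 4.55e-07), so chance cannot be excluded.

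Abundant genes were nearly absent from the knockdown tables: 20 of 1350 genes with at least 50 FPKM in the 8-cell stage column lay under 1 FPKM in the 8-cell knockdown controls, such as Ppia (978 and 0.229 FPKM) and Sumo2 (534 FPKM and listed at 0). A change particular to the injected 8-cell embryos is argued against, since 17 of the 20 were also under 1 FPKM in the blastocyst controls. A near-identical copy was found for 18 of 19 such genes in the annotation (94.7%), against 367 of 1285 others (28.6%; Fisher's exact p = 3.03e-09), so reads shared with near-identical copies and handled differently in the 2 kinds of table are a likely source. Bex1 (77.6 and 0.111 FPKM) has no copy and stays unexplained.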

How the results depend on the processing

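Settings chosen after the data were seen were the fits by library type, the median scaling, variance model and filters for the gene lists, and every setting of the stage-derived lists except the estimated correlation, the block and the larger stage difference. The others were set beforehand. For the changes below the cause was not tested.

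In the Nr5a2 knockdown, where 128 genes rose and 57 fell, a pseudocount of 0.1 gave 73 and 35, no filter 7 and 4, median scaling 75 higher, quantile normalization 68 higher, and the replicate number as a block 37 and 18. Without 1 library 13 to 177 rose and 8 to 108 fell. The Nr5a2 difference was -1.76 without a filter (adjusted p = 0.0845), and -1.95 to -1.64 without 1 library. In the Gata4 knockdown, where 0 rose and 3 fell in limma (202 at unadjusted p under 0.05), a pseudocount of 0.1 gave 1 lower. No filter (558 at unadjusted p under 0.05), a mean of at least 5 FPKM (95), median scaling (505), quantile normalization (484), the library type as a covariate (704), the same with median scaling (645), and the libraries with Rn45s alone (736) gave 0. Those without Rn45s alone gave 1 higher and 0 lower (557), and the block 4 higher and 14 lower. Without 1 library 0 to 5 rose and 1 to 25 fell. The Gata4 difference was -2.26 to -1.31 without 1 library.

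Of 4 lists called in the Nr5a2 knockdown, an estimated correlation and fry called 0, and fits without 1 library called 3 to 6. In the Gata4 knockdown, where 7 were called, an estimated correlation and fry called 0, with or without the library type and median scaling. The libraries without Rn45s alone called 3, of which pluripotency was among the 7 and p53 response and mitosis were not, and fits without 1 library called 4 to 7. The pluripotency list was not called in the Nr5a2 knockdown without a filter, nor in the Gata4 knockdown with the block (adjusted p = 0.229). Directions reversed in the libraries without Rn45s alone for primitive endoderm (adjusted p = 0.898), proteasome (0.663) and mitosis (0.0446), and with quantile normalization for oxidative phosphorylation (0.471).

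In the Nr5a2 knockdown, genes rising from 4-cell to 8-cell gave an adjusted p of 0.231 with an estimated correlation and 0.543 with fry, and 0.000185 to 0.0284 without 1 library. Genes falling there gave 0.00533 with fry, 0.0363 with median scaling, 0.0347 without a filter, 0.0451 with a mean of at least 5 FPKM, and 0.0336 to 0.339 without 1 library. In the Gata4 knockdown, genes rising and falling from 8-cell to ICM gave 0.0189 and 0.00209 with a stage difference of at least 2, 0.0190 each with quantile normalization, 0.0343 and 0.0105 with Rn45s, and 0.925 and 0.365 without. Without 1 library the 2 lists gave adjusted p-values of 0.00701 to 0.650 and 0.0119 to 0.650.

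In the 7 stage steps from oocyte to mESC, genes changed were 2136, 819, 5008, 2717, 997, 3284 and 3252. At least 20 FPKM gave 1245, 419, 2631, 1369, 395, 1748 and 1607, and a difference of at least 2 gave 432, 148, 2793, 593, 153, 1359 and 1200. A pseudocount of 5 gave 1356 from oocyte to zygote, 430 from zygote to early 2-cell, 1677 from 2-cell to 4-cell and 479 from 4-cell to 8-cell, and at least 1 FPKM gave 1517 from 4-cell to 8-cell.

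Of all values of the results above, 183 kept direction and call or stayed close, 74 moved, 16 gained a call and 4 lost one. Among the single genes, lists and parts of counts, 1381 values kept direction and call, 146 lost a call, 34 gained one, 116 moved and 4 reversed. No paired analysis was possible for the stage table because it has 1 value per stage. Replicate numbers did not pair the knockdown libraries: residual correlations of equal numbers were 0.041, 0.099, -0.124 and 0.017 for Nr5a2 and -0.135, 0.365 and -0.01 for Gata4. Depth limits low genes. At these sample sizes 19% of simulated changes of 1 log2 unit were recovered in the blastocyst libraries, whose library types were not simulated.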

Other observations

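All tests of other splits were chosen after the result was seen. The median of oxidative phosphorylation genes in the stage table was 9.08 FPKM in the MII oocyte, 39.0 in the 2-cell embryo, 92.1 in the 8-cell embryo, 223 in ICM and 232 in mESC, and that of proteasome subunits was 25.4, 67.7, 214, 205 and 136 FPKM at these stages. Glycolysis genes stayed between 2.91 and 9.24 FPKM up to the 8-cell stage and stood at 25.7 FPKM in ICM and 33.4 FPKM in mESC. Mitosis genes had medians of 103 FPKM in the oocyte, 40.4 FPKM at the 2-cell, 56.2 FPKM at the 4-cell and 49.1 FPKM at the 8-cell stage, 25.8 FPKM in ICM and 17.4 FPKM in mESC.

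Cholesterol synthesis genes had medians of 2.43 to 7.05 FPKM over the 8 stages, p53 response genes 1.55 to 4.96, DNA methylation genes 2.70 to 6.71, imprinted genes 0.215 to 0.596, interferon response genes 0.0286 to 0.214 and genes bound by NR5A2 in liver or gonad 0 to 0.140. Housekeeping genes had medians of 22.4 FPKM in the zygote and 325 FPKM in ICM. The lists of cumulus, sperm, fibroblast and blood genes had medians between 0 and 0.0631 FPKM. Some values at single stages were irregular: 10 of 78 ribosomal proteins were listed at 0 in the MII oocyte, Nolc1 was listed at 0 in the 2-cell and 8-cell embryo and at 213 FPKM in the 4-cell embryo, and Rn45s was listed at 6967 FPKM in the oocyte, 6829 in the early 2-cell embryo, 2555 in mESC and 0 at the other stages. No expression tool is named for the oocyte and early 2-cell embryo, while Cufflinks is named for mESC. Oaz1-ps, which has a near-identical copy, stood at 1.81e-06 and 0.000404 FPKM in the oocyte and early 2-cell embryo. It stood at 27.3 and 311 FPKM in the zygote and 2-cell embryo, and the cause was not tested.

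Each split of the libraries into groups of the same sizes was fitted in turn. For the Nr5a2 knockdown the real split was the only 1 of 35 to call as many as 185 genes (highest other 4), which argues against chance, as far as 35 splits can. For the pluripotency list the real split also gave the smallest p of the 35 (0.00241), but by a narrow margin, since a split that exchanges 1 control and 1 knockdown gave 0.0028. For the number of lists called (4), 9 of 35 splits gave as many (highest other 7), and for the p53 list 7 of 35 gave a p as small (0.000433, smallest other 4.76e-07), so chance cannot be excluded for these.

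For the Gata4 knockdown, 11 of 35 splits called as many as 3 genes, and the highest other, 4214 genes, came from the split that sets the 4 libraries with Rn45s against the 3 without, which points to a structure of the samples. As many as 7 lists were called in 16 of 35 splits (highest other 9). A p as small for the primitive endoderm list (1.09e-13) came in 4 of 35 (smallest other 1.68e-18), and for genes falling from 8-cell to ICM (0.0430) in 7 of 35 (smallest other 0.00174). Chance cannot be excluded for any of these 4 results.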
